A study of Homo sapiens with 6 samples.

How the data were processed

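RNA sequencing libraries of Jurkat cells, 3 incubated for 4 h with 10 µM flubendazole and 3 with vehicle, were read from 1 table of the whole series. The libraries were made with a stranded poly(A) messenger RNA kit and sequenced as 75 bp single-end reads, per the labels' protocols. The deposited values are raw read counts per Ensembl gene ID, with no normalization, in 1 column per library. Reads were counted with featureCounts on genome build GRCh38, with Subread 1.6.3 also named, per the submitters' processing notes. The aligner, the annotation release, the strand setting and any filter on reads are not given in the sources used here. Columns of the table carry short control and treated names with a number, and each was matched to the sample whose title has that treatment and that number.

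Counting with regard to strand was checked on the values. Of 145 gene models that lie inside a single exon of an expressed gene on the opposite strand, 108 had at least 1 read, and the median read density was 0.0050 of the host gene's, so opposite strands were kept apart in the deposited counts. Counts cannot show how reads matching several paralogs or pseudogenes were handled, so values of near-identical genes, the tubulins and ribosomal protein genes among them, are uncertain to that extent.

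The table holds 60675 gene IDs, of which 56558 matched a symbol in the supplied gene name tables. Gene IDs without a symbol took 0.168% to 0.187% of the counts and were kept in the library sizes and tests. Gene positions are the first start and last end of a gene's exons in the count table, on GRCh38, and gene classes, transcript sequences and GC content came from GENCODE release 29. No column belonged to another series and no sample was left out.

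Library totals ran from 47301760 to 54683206 counts. The 10 most abundant genes took 5.42% to 5.69% of a library. Before replicates were averaged, each pair of libraries was compared by a chi-square statistic over genes with at least 20 counts in the pair. Within groups it was 1.87 to 3.19 per degree of freedom, so no pair was within sampling noise and all 6 libraries were counted separately, and between groups it was 31.9 to 36.4. The first principal component of log2 CPM held 57.2% of the variance and separated the groups. The common biological coefficient of variation was 2.60%, a spread at which small differences can pass the test. Counts behind this precision are reads without molecular identifiers.

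The main test was edgeR 4.0.16 in R 4.3.3, with filterByExpr by group, which left 20746 genes, TMM scaling factors of 0.992 to 1.01, robust quasi-likelihood fits and the quasi-likelihood F test of flubendazole against vehicle without further covariates. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and no fold minimum was set. CPM values were computed from the counts with TMM-scaled library sizes, and log2 CPM with a prior count of 2 was used only for correlations and principal components. The SE of a log2 fold change is its size divided by the square root of the F statistic.

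Before the data were examined, 35 gene lists with 1135 symbols were fixed for a tubulin-binding compound in a T cell line, among them markers of other cell types and of RNA quality, and 1035 symbols were tested. Lists were tested with camera of limma 3.58.1 against all other genes, two-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, and list members were also adjusted over the list alone. Named genes follow a rule fixed at the same time. Its first part covers only genes with a gene symbol, an adjusted p under 0.05, at least 1 CPM in the higher group and no overlap between the groups' libraries. Among these it takes the 8 largest rises, the 8 largest falls, and the 5 higher and 5 lower with the smallest p. It adds every tested alpha- and beta-tubulin gene, up to 4 members with the smallest p of each other list, and PDCD1 and STAT3 whatever their result, 159 genes in all. Y-linked genes and XIST were left out.

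The procedure was tested on 1 set of simulated counts with the means, dispersion and library sizes of this comparison, in which 200 of 20746 genes were changed. The changed genes were drawn from those with a mean above 1 CPM, so the recovery does not cover less abundant genes. Of 50 genes at each size, edgeR recovered 24.0% at 1.1-fold, 88.0% at 1.25-fold, 88.0% at 1.5-fold and 100% at 2-fold, and it called 11 unchanged genes, 6.83% of its calls, above the nominal 5%. A change of 1.2-fold planted in the integrated stress response list was called, and of the 34 other lists 1 was called, the aryl hydrocarbon receptor list, which shares SLC7A5 with the planted list.

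Alternatives fixed in advance were DESeq2 1.42.0, limma-voom, 3 other scalings, no filter and a filter of 1 CPM in 3 libraries, the replicate number as a block, removal of mitochondrial genes, fits without robust estimation, each library left out in turn, a test against a 1.5-fold minimum, a threshold of 0.01, camera with an estimated correlation and fry. Libraries thinned to 1 depth, an offset that removes each library's trend with gene length and GC content, and camera on ranks were added after the data were seen. The GC value was known for 20585 of the tested genes, 99.2%.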

Results

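Gene expression was measured by RNA sequencing in Jurkat cells, an established human T cell leukaemia line, after 4 h in 10 µM flubendazole or in vehicle. Flubendazole is a benzimidazole anthelmintic that binds tubulin and blocks its assembly into microtubules. The comparison asks which transcripts differ in level between treated and untreated cells at that time. Each group held 3 libraries, and read counts per gene totalled 48712965, 47301760 and 48659839 in the vehicle libraries and 53324252, 50497939 and 54683206 in the flubendazole libraries. Every treated library was therefore deeper than every vehicle library, and its share of counts on mitochondrial genes was also higher, at 5.22% to 5.34% against 5.07% to 5.19%. Libraries of the same group had Pearson correlations of log2 CPM, counts scaled to library size, of 0.996 to 0.997 across genes, and libraries of different groups 0.991. Levels are given as mean CPM ± SD and log2 fold changes of flubendazole over vehicle as estimate ± SE, with n = 3 libraries per group throughout.

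Of 11 tested genes for alpha- and beta-tubulin, the drug's target, 9 fell and TUBA8 and TUBB3 did not pass, and a set of genes with little or moderate expression in vehicle rose many fold. TUBB, the main beta-tubulin transcript in these cells, went from 2158 ± 27.6 CPM to 712 ± 14.1 CPM, a log2 fold change of -1.60 ± 0.02. ENPP1, which encodes an ectonucleotide pyrophosphatase that hydrolyses extracellular nucleotides, went from 27.1 ± 0.34 CPM to 386 ± 5.7 CPM, a log2 fold change of 3.83 ± 0.03. Of 45 tested amino acid and stress genes listed as targets of the transcription factor ATF4, 39 rose and 1 fell (camera with an estimated correlation, adjusted p = 0.0035). All 41 tested genes of the MYC and ribosome biogenesis list fell (camera with an estimated correlation, adjusted p = 0.0231). Of 30 genes of cholesterol synthesis and uptake, 23 fell and 1 rose (same test, adjusted p = 0.0091).

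Of 20746 genes tested with edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, 8515 differed between the groups, 4270 higher and 4245 lower in flubendazole. Most of these differences were small. The median fold size of the genes past the threshold was 1.18, with quartiles of 1.11 and 1.35. Among the genes past the threshold, 1338 differed by at least 1.5-fold, 903 of them higher and 435 lower, and 469 by at least 2-fold, 338 of them higher and 131 lower. The 3 treated libraries lay all above or all below the 3 vehicle libraries for 10223 genes, 49.3% of those tested, where chance alone gives 10%. Among protein-coding genes, 3476 of 13790 rose and 3631 fell, while among long non-coding RNAs 508 of 3412 rose and 275 fell.

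**Figure D1:**
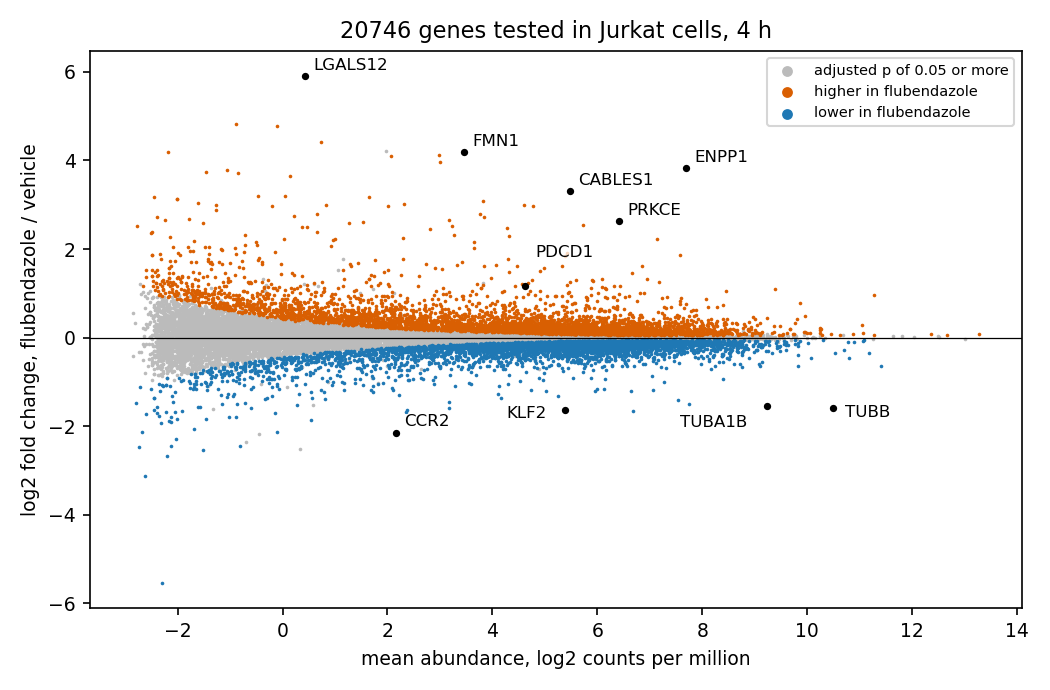
Log2 fold change of flubendazole over vehicle against mean abundance in log2 CPM, with 1 point for each of the 20746 genes tested; orange points are higher and blue points lower in flubendazole at an adjusted p under 0.05, grey points did not pass, and black points mark 10 named genes. The tubulin genes TUBB and TUBA1B lie far below 0 at high abundance, and ENPP1 is the point highest above 0 among the genes of similar abundance that are labelled.

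Genes without a symbol were not ranked. Among genes with a symbol, at least 1 CPM in the higher group and no overlap between the groups' libraries, 8 had the largest rises. They were LGALS12, PRSS56, ECEL1, FMN1, ABCA4, IGLON5, ENPP1 and SIRPB2. LGALS12, which encodes the galactoside-binding lectin galectin-12, had 6 reads in the vehicle libraries together and 421 in the flubendazole libraries, a log2 fold change of 5.91 ± 0.26 (edgeR with Benjamini-Hochberg adjustment, adjusted p = 8.13e-17). PRSS56, a serine protease gene, had 5 reads against 167 and a log2 fold change of 4.82 ± 0.37. ECEL1, a gene of the endothelin-converting enzyme family, rose by 4.41 ± 0.20. FMN1 encodes formin 1, a nucleator of actin filaments, and rose from 1.14 ± 0.26 CPM to 20.8 ± 0.30 CPM. The lipid transporter gene ABCA4, best known from photoreceptors, rose by 4.13 ± 0.12 from 0.852 ± 0.32 CPM. IGLON5, a neuronal cell adhesion gene, rose by 4.09 ± 0.12, and SIRPB2, a signal-regulatory protein gene, by 3.66 ± 0.26. ENPP1 lies on chromosome 6 of GRCh38 at positions 131808016 to 131895155, and its difference had the smallest p of all genes, with an adjusted p = 1.55e-34 by the same test.

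The other rises with the smallest p were in signalling genes expressed at moderate levels in vehicle. PRKCE, which encodes the epsilon isoform of protein kinase C, rose from 23.7 ± 0.12 CPM to 147 ± 1.1 CPM. CABLES1, whose product binds cyclin-dependent kinases, rose from 8.17 ± 0.34 CPM to 81.1 ± 2.5 CPM. RASSF8, a gene of the Ras association domain family, rose by 2.23 ± 0.03, and PDE4D, which encodes a phosphodiesterase that degrades cyclic AMP, by 2.54 ± 0.04.

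The largest falls by the same rule were in CCR2, IL26, ZBTB16, TRIM67, TUBB4A, TUBBP1, KLF2 and MDGA1. CCR2, the receptor of a monocyte chemoattractant chemokine, went from 7.30 ± 0.26 CPM to 1.65 ± 0.047 CPM, with a log2 fold change of -2.15 ± 0.09 (edgeR with Benjamini-Hochberg adjustment, adjusted p = 4.84e-17). The cytokine gene IL26 had a log2 fold change of -2.13 ± 0.21, and ZBTB16, a zinc finger transcription factor gene of innate-like T cells, one of -1.87 ± 0.16. TRIM67, of the tripartite motif family, and MDGA1, which encodes a membrane-anchored adhesion protein, had values of -1.70 ± 0.20 and -1.63 ± 0.09. KLF2, a transcription factor gene of T cell quiescence and trafficking, went from 63.2 ± 1.1 CPM to 20.4 ± 0.48 CPM. TUBBP1 is annotated as a beta-tubulin pseudogene and had a log2 fold change of -1.66 ± 0.03, close to that of TUBB, and reads of the 2 genes may have been divided between them in the deposited counts.

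Of the 11 alpha- and beta-tubulin genes tested, 9 fell and none rose over all genes tested, and adjusted over the list alone 9 fell and TUBB3 rose. TUBA1B went from 899 ± 13.0 CPM to 306 ± 6.4 CPM, and TUBB4B from 316 ± 6.0 CPM to 111 ± 3.5 CPM. The log2 fold changes of TUBA1C and TUBA1A were -1.41 ± 0.03 and -1.21 ± 0.03. The less abundant TUBB4A, TUBA4A, TUBB2A and TUBB6 fell by 1.69, 1.19, 0.94 and 0.86 on the log2 scale. TUBA8 and TUBB3, at about 1.4 CPM and under 1 CPM, had values of 0.03 ± 0.15 and 0.46 ± 0.21 and did not pass over all genes tested (adjusted p = 0.897 and adjusted p = 0.0809, edgeR with Benjamini-Hochberg adjustment). TUBB lies on chromosome 6 of GRCh38 at 30720201 to 30725426, TUBB4B on chromosome 9 at 137241213 to 137243707, and TUBA1B, TUBA1A and TUBA1C lie near each other on chromosome 12, from 49127782 to 49274603. The median log2 fold change of the list was -1.21, and the list stood below all other genes (camera with Benjamini-Hochberg adjustment over 35 lists, adjusted p = 1.82e-69, and adjusted p = 0.0035 with an estimated correlation). These genes share stretches of sequence, so reads of near-identical members may have been assigned to each other.

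**Figure D2:**
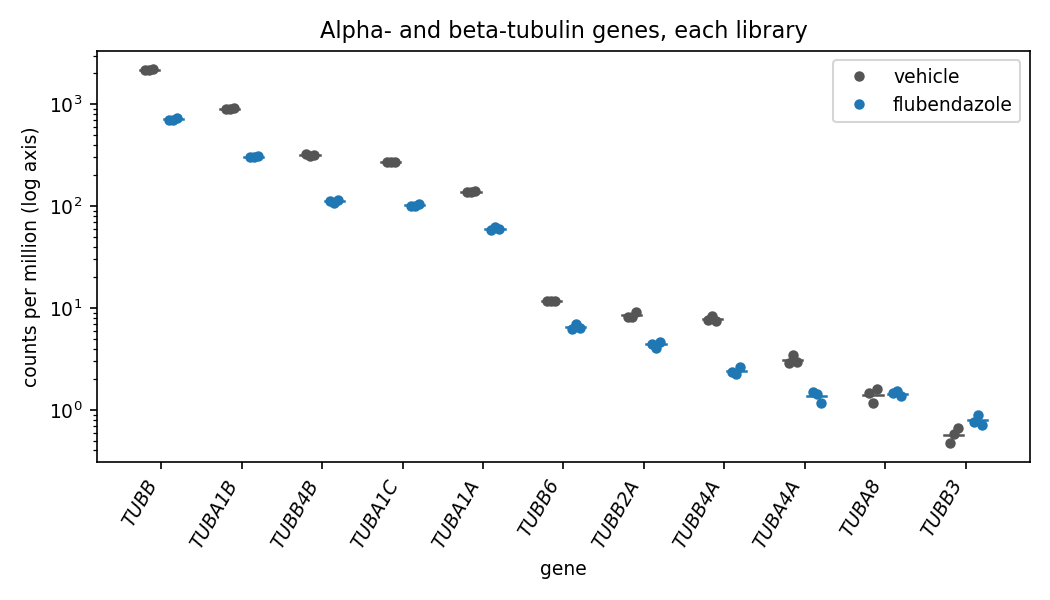
Level of each tested alpha- and beta-tubulin gene in CPM on a log axis; each point is 1 of 6 libraries, grey for vehicle and blue for flubendazole, and short lines are group means of 3 libraries. In 9 of the 11 genes all flubendazole points lie below all vehicle points, from TUBB at 2158 against 712 CPM to TUBA4A at 3.12 against 1.37 CPM, and TUBA8 and TUBB3 are the exceptions.

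Of the 4 tested gamma-, delta- and epsilon-tubulin genes, TUBG1 fell, TUBE1 rose, and TUBD1 and TUBG2, at 0.03 ± 0.05 and 0.02 ± 0.05, did not pass. TUBG1, which encodes the gamma-tubulin that nucleates microtubules, went from 60.5 ± 1.3 CPM to 32.0 ± 1.1 CPM, a log2 fold change of -0.92 ± 0.03, while TUBE1, for epsilon-tubulin, rose by 0.22 ± 0.03. Of the 13 tested gamma-, delta- and epsilon-tubulin and ring complex genes, TUBE1, NEDD1 and TUBGCP6 rose, TUBG1 and MZT1 fell, and 8 did not pass, and the counts adjusted over the list alone were also 3 and 2. The list's test did not pass (camera, adjusted p = 0.566), and its median of 0.01 and mean of -0.04 differed in sign. NEDD1 and TUBGCP6, which attach and build the gamma-tubulin ring, had log2 fold changes of 0.12 ± 0.03 and 0.14 ± 0.04.

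Of 31 tested factors that fold, modify and degrade tubulin, 16 fell and 5 rose over all genes tested, and 19 and 5 adjusted over the list alone. TTLL12, of the tubulin tyrosine ligase family, had a log2 fold change of -0.42 ± 0.03, and CCT3, CCT4 and CCT6A, subunits of the cytosolic chaperonin that folds tubulin and actin, had values of -0.31 ± 0.02, -0.33 ± 0.02 and -0.32 ± 0.03. The members that rose were ATAT1, HDAC6, VASH2, TTL and SIRT2, which add or remove modifications of tubulin, with log2 fold changes of 0.07 to 0.18. The list passed (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0020), but not with adjusted p = 0.308 with an estimated correlation. Among 29 microtubule-binding and severing proteins, 11 rose and 10 fell, and 11 and 11 adjusted over the list alone. In that list MAP7, a microtubule-stabilising protein gene, had a log2 fold change of -0.64 ± 0.06, while CKAP5, MAPRE2 and CLASP1, which act at growing microtubule ends, rose by 0.20 ± 0.02, 0.21 ± 0.03 and 0.24 ± 0.03. The list did not pass (camera, adjusted p = 0.961), with a median of 0.0037 and a mean of -0.02.

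Of 61 tested mitotic (G2/M) genes, 42 rose and 4 fell over all genes tested, and 45 and 5 adjusted over the list alone, with a median log2 fold change of 0.18. PRC1 and KIF20A, which act at the central spindle, rose by 0.33 ± 0.02 and 0.35 ± 0.03, and NUF2, a kinetochore gene, and CKAP2L, a spindle gene, by 0.36 ± 0.03 and 0.37 ± 0.03. The members that fell were CDC20, TMPO, ANP32E and CTCF, with log2 fold changes of -0.13 to -0.09. The list passed (camera with Benjamini-Hochberg adjustment, adjusted p = 3.82e-09), but adjusted p = 0.224 with an estimated correlation. DNA replication genes of the G1/S transition went both ways, with 12 of 55 higher and 21 lower, 14 and 21 adjusted over the list alone. In that group BRIP1 and EXO1, a helicase and an exonuclease of DNA repair, rose by 0.33 ± 0.03 and 0.24 ± 0.03. RRM2, a ribonucleotide reductase subunit gene, and MCM4, of the replicative helicase, had values of -0.26 ± 0.02 and -0.22 ± 0.02, and the list did not pass (camera, adjusted p = 0.496).

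Actin genes and targets of the serum response factor were mostly higher. Of 31 tested, 20 rose and 5 fell, the same numbers as adjusted over the list alone, with a median log2 fold change of 0.19. TPM4, a tropomyosin gene, went from 682 ± 3.37 CPM to 1171 ± 21.9 CPM, a rise of 0.78 ± 0.02. FHL2, a LIM domain cofactor gene, rose by 0.73 ± 0.04, MYH9, the non-muscle myosin heavy chain gene, by 0.49 ± 0.02 and CORO1A, an actin-binding coronin gene, by 0.45 ± 0.02. The 5 that fell were TAGLN2, TPM1, FHL3, PFN1 and TPM3, with log2 fold changes of -0.24 to -0.07. The list passed (camera with Benjamini-Hochberg adjustment, adjusted p = 3.80e-09), but adjusted p = 0.162 with an estimated correlation.

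Genes of the integrated stress response formed the group with the most widespread rise. This programme is driven by ATF4 and raises amino acid synthesis, transport and transfer RNA charging. Of 45 tested, 39 rose and only WARS1 fell over all genes tested, and 39 rose and 2 fell adjusted over the list alone. VLDLR, a lipoprotein receptor gene, rose from 35.6 ± 0.27 CPM to 85.8 ± 0.64 CPM, and STC2, which encodes stanniocalcin 2, from 34.4 ± 0.50 CPM to 85.3 ± 2.2 CPM. DDIT4, a repressor of mTORC1 signalling, and SLC1A4, a neutral amino acid transporter, rose by 0.77 ± 0.02 and 0.82 ± 0.03. Members that did not pass were TRIB3, GDF15, EPRS1, ALDH1L2 and DDIT3, and DDIT3, which encodes the stress factor CHOP, had a log2 fold change of -0.02. The median of the list was 0.40 (camera with Benjamini-Hochberg adjustment, adjusted p = 2.59e-42, and adjusted p = 0.0035 with an estimated correlation).

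The unfolded protein response of the endoplasmic reticulum divided. Of 30 tested members, 6 rose and 18 fell, and the counts adjusted over the list alone were equal to these. HERPUD1 and EDEM1, which act in degradation of misfolded proteins of the reticulum, rose by 0.92 ± 0.02 and 0.70 ± 0.02. The chaperone genes CALR and HSPA5 had log2 fold changes of -0.45 ± 0.02 and -0.46 ± 0.02, and the list did not pass (camera, adjusted p = 0.116). Heat shock protein genes were mostly lower, with 17 of 26 fallen and DNAJB6 risen over all genes tested, and 17 and 2 adjusted over the list alone. HSPH1, FKBP4, HSP90AB1 and STIP1, chaperones and co-chaperones of the HSP70 and HSP90 systems, had log2 fold changes of -0.41 ± 0.02, -0.46 ± 0.03, -0.35 ± 0.02 and -0.39 ± 0.02. The heat shock list passed (camera with Benjamini-Hochberg adjustment, adjusted p = 2.43e-10), but adjusted p = 0.098 with an estimated correlation.

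Antioxidant genes driven by NRF2 were also lower on balance, with 14 of 24 fallen and 2 risen, and 15 and 2 adjusted over the list alone. GSR, the glutathione reductase gene, and TKT and PGD, of the pentose phosphate pathway, had log2 fold changes of -0.44 ± 0.03, -0.30 ± 0.02 and -0.27 ± 0.02. SLC7A11, the cystine transporter gene that ATF4 also drives, rose by 0.85 ± 0.03, as did NFE2L2, which encodes NRF2, by 0.18. The list passed (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0054), but adjusted p = 0.224 with an estimated correlation. Of 8 tested aryl hydrocarbon receptor genes, SLC7A5 rose by 0.17 ± 0.02 and NQO1 had a value of -0.36 ± 0.05, and these were also the only calls adjusted over the list alone. The receptor's classical targets CYP1A1 and CYP1B1 had values of 0.43 ± 0.24 and -0.15 ± 0.09 and did not pass (adjusted p = 0.173 and adjusted p = 0.180, edgeR with Benjamini-Hochberg adjustment). CYP1A1 passed only when vehicle replicate 1 was left out, and the list did not pass (camera, adjusted p = 0.961).

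Of 30 tested genes of cholesterol synthesis and uptake, 23 fell and ABCG1, a sterol exporter gene, rose, and 24 and 1 adjusted over the list alone. HMGCS1, the synthase upstream of mevalonate, went from 444 ± 11 CPM to 231 ± 9.5 CPM, a log2 fold change of -0.94 ± 0.03. SQLE, an enzyme of sterol synthesis, had a value of -0.71 ± 0.02, and INSIG1, which retains the sterol sensor in the endoplasmic reticulum, one of -0.59 ± 0.02. The list's median was -0.28 (camera with Benjamini-Hochberg adjustment, adjusted p = 4.61e-21, and adjusted p = 0.0091 with an estimated correlation). Of 22 fatty acid synthesis genes, 13 fell and LPIN1 and ACACB rose, and 14 and 2 adjusted over the list alone. FASN, the fatty acid synthase gene, had a log2 fold change of -0.63 ± 0.03, SCD, the stearoyl desaturase gene, one of -0.46 ± 0.02, and ACLY and ACACA, which supply acetyl and malonyl coenzyme A, values of -0.33 ± 0.02 and -0.36 ± 0.02. That list passed (camera with Benjamini-Hochberg adjustment, adjusted p = 3.80e-05), but adjusted p = 0.0566 with an estimated correlation.

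All 41 tested members of the MYC and ribosome biogenesis list fell, over all genes tested and adjusted over the list alone. MYC itself, a transcription factor gene of cell growth, went from 204 ± 3.3 CPM to 103 ± 3.1 CPM, a log2 fold change of -0.99 ± 0.03. PUS7, a pseudouridine synthase gene, SRM, the spermidine synthase gene, and MYBBP1A, a nucleolar gene, had values of -0.76 ± 0.03, -0.66 ± 0.03 and -0.67 ± 0.03. The list's median was -0.37 (camera with Benjamini-Hochberg adjustment, adjusted p = 1.66e-42, and adjusted p = 0.0231 with an estimated correlation). Cytosolic ribosomal protein genes did not move as a group, with 7 of 78 higher and 10 lower, 6 and 8 adjusted over the list alone, a median of 0.0071 and a mean of -0.0039 (camera, adjusted p = 0.961). In that list RPL13A and RPS3 rose by 0.28 ± 0.03 and 0.11 ± 0.02, and RPS26 and RPS15 had values of -0.33 ± 0.06 and -0.14 ± 0.03, and each of these genes has processed pseudogenes that may share its reads.

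**Figure D3:**
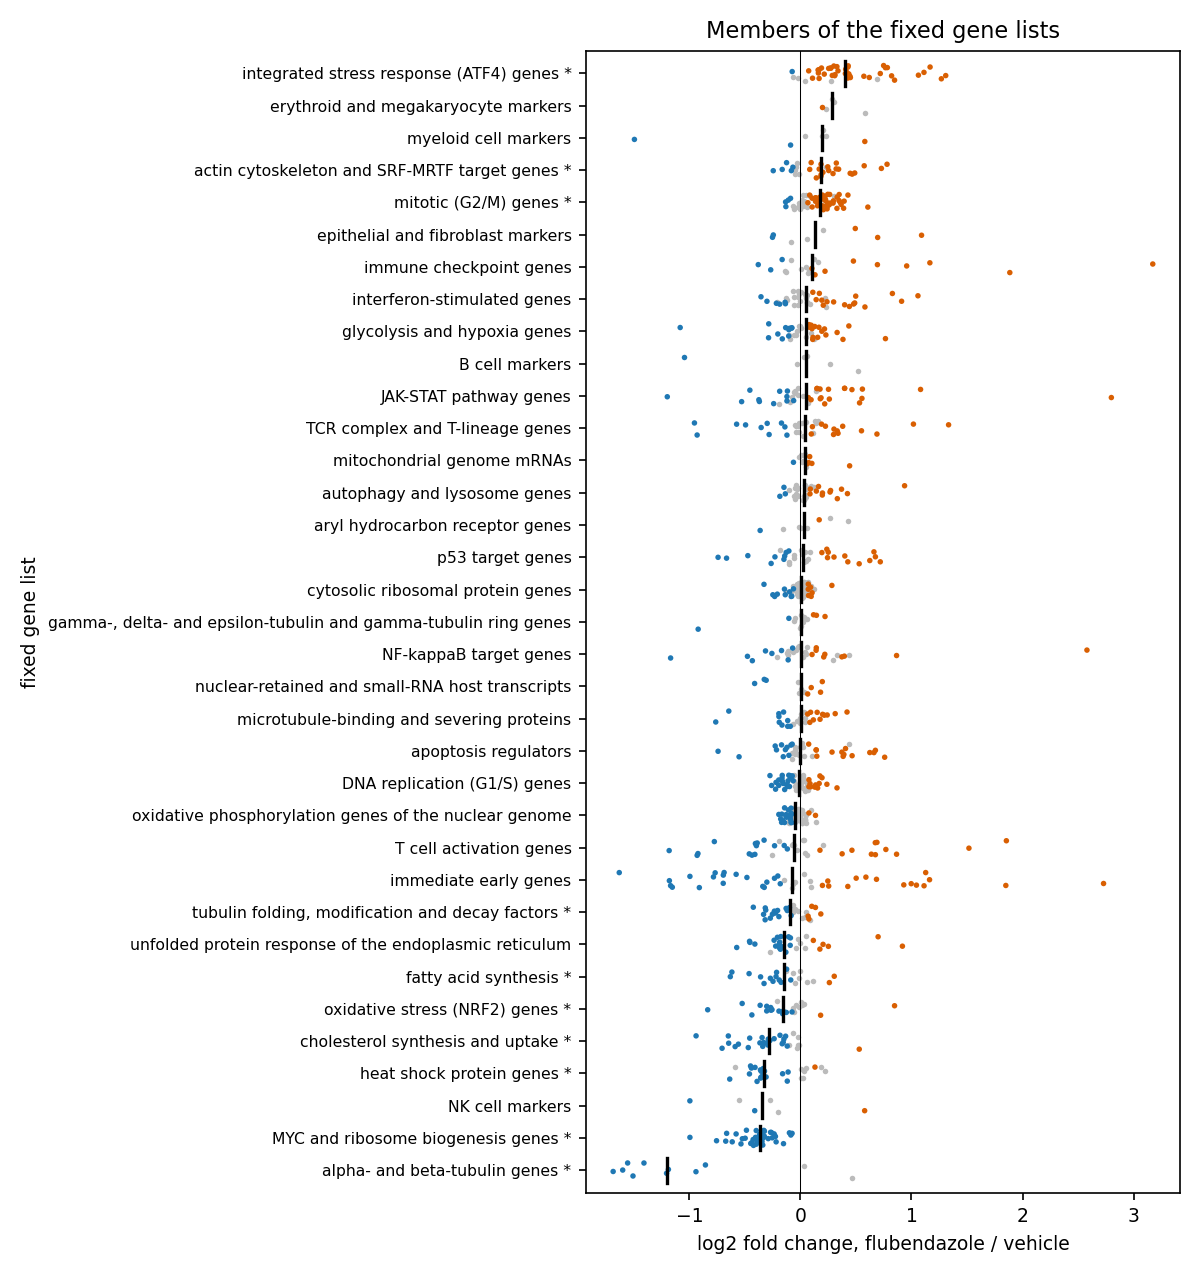
Log2 fold change of flubendazole over vehicle for the tested members of each of the 35 fixed gene lists; each point is a gene, orange where it was higher and blue where it was lower at an adjusted p under 0.05 and grey where it did not pass, black bars are list medians, and an asterisk marks the 10 lists that passed the camera test. The medians run from -1.21 for the alpha- and beta-tubulin genes to 0.40 for the integrated stress response.

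Immediate early genes went strongly in both directions. Of 41 tested, 15 rose and 19 fell, and 15 and 20 adjusted over the list alone. DUSP4, a phosphatase gene of MAP kinases, rose from 18.2 ± 1.4 CPM to 65.7 ± 1.1 CPM, and JUN, a subunit gene of the AP-1 transcription factor, from 53.3 ± 1.3 CPM to 119 ± 3.3 CPM. IER3, an early response gene of cell survival, had a log2 fold change of -1.17 ± 0.03 and KLF2 one of -1.63 ± 0.03. The list did not pass (camera, adjusted p = 0.961), and its median of -0.08 and its test were below 0 while its mean was 0.01. NF-kappaB targets gave 9 of 32 higher and 8 lower, and 10 and 8 adjusted over the list alone. BCL3, a nuclear cofactor gene of that factor, rose by 2.58 ± 0.14 from 0.686 ± 0.12 CPM, while CD83 and IRF1, genes of lymphocyte activation and interferon signalling, had values of -0.48 ± 0.03 and -0.43 ± 0.04. The NF-kappaB list did not pass (camera, adjusted p = 0.534), with its test below 0 and its median of 0.0063 and mean of 0.08 above 0.

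Genes of T cell function also changed in both directions. Of 36 tested T cell activation genes, 11 rose and 14 fell, and 11 and 15 adjusted over the list alone. CD40LG, the ligand by which T cells help B cells, went from 185 ± 2.2 CPM to 81.7 ± 1.4 CPM, and GATA3, a transcription factor gene of the T lineage, from 93.3 ± 0.54 CPM to 49.0 ± 2.4 CPM. CD28, a costimulatory receptor gene, rose by 0.69 ± 0.03 and FAS, a death receptor gene, by 0.68 ± 0.05. The list did not pass (camera, adjusted p = 0.300), and its median of -0.06 and its test were below 0 while its mean was 0.04. Of 37 T cell receptor complex and T-lineage genes, 13 rose and 10 fell, the same numbers as adjusted over the list alone (camera, adjusted p = 0.296). CD5, an inhibitory coreceptor gene, rose from 38.8 ± 1.4 CPM to 97.8 ± 2.2 CPM.

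PDCD1, which encodes the inhibitory receptor PD-1, rose from 15.1 ± 0.79 CPM to 33.9 ± 1.1 CPM, a log2 fold change of 1.17 ± 0.05 (edgeR with Benjamini-Hochberg adjustment, adjusted p = 6.93e-18), with all 3 treated libraries above all 3 vehicle libraries. The gene lies on chromosome 2 of GRCh38 at 241849881 to 241858908. STAT3, a transcription factor gene of cytokine signalling, rose from 270 ± 1.4 CPM to 322 ± 1.7 CPM, a log2 fold change of 0.25 ± 0.02. Of 21 tested immune checkpoint genes, 9 rose and TOX, PVR and TOX2 fell, and 9 and 3 adjusted over the list alone (camera, adjusted p = 0.284). NT5E, an ectonucleotidase gene, rose by 0.96 ± 0.08, CD276, a ligand gene of the B7 family, by 3.17 ± 0.52 to a level of only 0.332 ± 0.083 CPM, and TOX, a transcription factor gene of exhausted T cells, had a value of -0.38 ± 0.03.

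In the JAK-STAT list 18 of 42 members rose and 11 fell, the same numbers as adjusted over the list alone (camera, adjusted p = 0.296). STAT4, a transcription factor gene of interleukin-12 signalling, rose from 3.41 ± 0.30 CPM to 23.7 ± 1.3 CPM. The phosphatase gene PTPN6 went the other way, from 86.6 ± 1.6 CPM to 37.7 ± 0.79 CPM, and the receptor genes IFNAR2 and IL10RB rose by 0.56 ± 0.02 and 0.53 ± 0.03. Of 44 interferon-stimulated genes, 16 rose and 6 fell, and the counts adjusted over the list alone were also 16 and 6. The guanylate-binding protein genes GBP1 and GBP2 rose by 0.91 ± 0.03 and 1.06 ± 0.05, the antiviral gene MX2 by 0.83 ± 0.06 and STAT2 by 0.40 ± 0.03. The interferon list stood near the threshold (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0563) and passed when vehicle replicate 2 or flubendazole replicate 1 was left out.

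Among 34 p53 targets 12 rose and 9 fell, the same numbers as adjusted over the list alone (camera, adjusted p = 0.296). PMAIP1, the gene of the death-promoting protein NOXA, and SESN2, a stress-induced gene, rose by 0.66 ± 0.03 and 0.72 ± 0.04. SESN2 is also a member of the integrated stress response list. AEN, a nuclease gene, had a log2 fold change of -0.47 ± 0.03. Of 39 apoptosis regulators, 14 rose and 11 fell, and 15 and 12 adjusted over the list alone. BCL2, a survival gene, and APAF1, a gene of the caspase-activating apoptosome, rose by 0.38 ± 0.03 and 0.39 ± 0.03. That list did not pass (camera, adjusted p = 0.463), and its median was -0.0059 with a mean of 0.08 and a test above 0. Autophagy and lysosome genes had 12 of 40 higher and LAMP1, TFE3 and TFEB lower, and 12 and 3 adjusted over the list alone (camera, adjusted p = 0.300). The autophagy kinase gene ULK1 rose by 0.37 ± 0.03, WIPI2, of the growing autophagosome, by 0.20 ± 0.02, the lysosomal hydrolase gene GLA by 0.33 ± 0.04 and the cholesterol exporter gene NPC1 by 0.20 ± 0.03.

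Glycolysis and hypoxia genes gave 16 of 39 higher and 11 lower, the same numbers as adjusted over the list alone (camera, adjusted p = 0.462). VEGFA, an angiogenic factor gene, rose by 0.44 ± 0.03, while EGLN3, an oxygen sensor gene, and PKM, the pyruvate kinase gene, had values of -1.08 ± 0.06 and -0.29 ± 0.02. Of 74 nuclear genes of oxidative phosphorylation, 20 fell and UQCRB and SDHA rose, and 17 and 2 adjusted over the list alone (camera, adjusted p = 0.231). COX5A, CYC1, ATP5MC1 and ATP5MC3, subunits of the respiratory chain and ATP synthase, had log2 fold changes of -0.17 ± 0.03, -0.16 ± 0.03, -0.18 ± 0.03 and -0.13 ± 0.03. Of 13 messenger RNAs of the mitochondrial genome, 5 rose and MT-ND5 fell, and 6 and 1 adjusted over the list alone, in libraries whose mitochondrial share was higher in every treated sample (camera, adjusted p = 0.480). MT-ND2 and MT-CO1 rose by 0.10 ± 0.02 and 0.07 ± 0.02, and the rises of MT-ND4L, 0.08 ± 0.02, and MT-ND4, 0.06 ± 0.02, did not pass when some single libraries were left out. Of 11 nuclear-retained and small-RNA host transcripts, 4 rose and 3 fell, the same numbers as adjusted over the list alone (camera, adjusted p = 0.811). The host genes SNHG15 and SNHG12 had values of -0.33 ± 0.03 and -0.31 ± 0.03, SNHG5 and NEAT1, the scaffold RNA of paraspeckles, rose by 0.18 ± 0.03 and 0.20 ± 0.03, and the median of 0.0037 and mean of -0.05 of that list differed in sign.

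None of the 5 lists of markers of other cell types passed (camera, adjusted p = 0.389 to adjusted p = 0.999). Of 6 tested B cell markers, CD22 fell, from 0.458 ± 0.085 CPM to 0.221 ± 0.068 CPM, and CD79A, at 15.9 ± 0.41 CPM and 16.2 ± 0.51 CPM, and CD79B did not pass. Of 7 myeloid markers, S100A9 and AIF1 fell and CD14 rose, and FCER1G did not pass, with S100A9 at 0.660 ± 0.12 CPM in vehicle and 0.233 ± 0.048 CPM in flubendazole. Of 6 natural killer cell markers, GZMA, a granzyme gene that cytotoxic T cells also use, and NCR3 fell and NCAM1 rose, and NKG7 did not pass, and GZMA had a log2 fold change of -0.41 ± 0.04. Of 5 erythroid and megakaryocyte markers, EPOR rose and ITGA2B, KLF1 and SLC4A1 did not pass. Of 8 epithelial and fibroblast markers, COL1A1, CDH1 and CLDN4 rose and THY1 and KRT8 fell, with COL1A1 at 0.49 ± 0.06 and THY1 at -0.25 ± 0.05. Adjusted over the list alone the counts were the same except that no erythroid or megakaryocyte marker passed. The calls of CD22, CD14, AIF1, NCR3, NCAM1, EPOR, CDH1 and KRT8 were lost with DESeq2 and, except for that of CD14, also when at least 1 library was left out, and those of AIF1 and EPOR in further settings. The median and mean of the B cell list, 0.05 and -0.03, and of the myeloid list, 0.19 and -0.05, differed in sign.

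Altogether 10 of the 35 lists passed the camera test, 3 higher and 7 lower. With an estimated correlation in place of the preset one, 4 of these calls held, those of the alpha- and beta-tubulin, integrated stress response, cholesterol, and MYC and ribosome biogenesis lists. Members named above for lying in a group of 5 or fewer, beyond the rule for named genes, were chosen after their values were seen. The labels do not say that the libraries came from separate cultures, so the p-values measure only the spread among these samples, which may be technical.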

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

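The thinned libraries, the length and GC offset and camera on ranks were chosen after the data were seen, and the other alternatives before. Across filters, scalings, limma-voom, removal of mitochondrial genes, fits without robust estimation and the 0.01 threshold, 6589 to 8557 genes passed, DESeq2 called 6615, of which 6579 were shared, and with a library left out 7572 to 8259 passed with smaller groups. The balance of 4270 higher and 4245 lower moved to 4648 and 3909 with upper-quartile factors and to 3885 and 5197 with the length and GC offset. No gene called in the main fit changed sign in these settings, except 41 with that offset, counted whether or not they passed there. Tested against a 1.5-fold minimum, 455 genes passed, 323 higher and 132 lower, a stricter question by construction. With an estimated correlation 4 of the 10 list calls held. All 10 held with camera on ranks, which added the unfolded protein response and oxidative phosphorylation lists, and with fry, which called 24 lists and asks whether a list's own genes move on balance, without regard to other genes. Whether the replicate numbers pair the samples was not settled. Correlations were 0.08, 0.01 and 0.03 between samples of the same number and -0.0755 to 0.0432 between different numbers. Flubendazole 2 correlated better with vehicle 3 than with its own number. Replicate 1 was highest on the second principal component in both groups, at 19.3 in vehicle and 10.3 in flubendazole. With the numbers as a replicate block 9453 genes passed, more than the 8515 of the main fit, with 8496 shared. The list calls were the same 10. A replicate effect shared by the groups is therefore not excluded.

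TUBA8, which did not pass, had a log2 fold change of -0.0905 without vehicle replicate 2, -0.0148 without flubendazole replicate 2 and 0.124 without vehicle replicate 3; the cause was not tested. AIF1 also lost its call with the stricter filter, upper-quartile factors, library size only, fits without robust estimation, limma-voom and the length and GC offset, and EPOR without a filter and after thinning. CYP1A1 passed without vehicle replicate 1 (0.75, adjusted p = 0.0278). The calls of AIF1, CD14, CD22, CDH1, EPOR, KRT8, NCAM1 and NCR3 were lost with DESeq2, at adjusted p = 0.0503 for CD14 up to adjusted p = 0.202 for EPOR, and those of MT-ND4 and MT-ND4L with single libraries left out (MT-ND4 also without a filter), at up to adjusted p = 0.0948 and adjusted p = 0.0705. The interferon list passed without vehicle replicate 2 (adjusted p = 0.0388) or flubendazole replicate 1 (adjusted p = 0.0402). All other named genes kept their direction and side of the threshold in every setting that tested them. The filter of 1 CPM in 3 libraries left some low-abundance genes untested, PRSS56, S100A9 and CD276 among them. The recovery of 24.0% at 1.1-fold came from simulated counts in which far fewer genes were changed than passed here. Adjustment is stricter with fewer changed genes, so that share does not give the recovery in this comparison. The fold sizes of the genes that passed here had a lower quartile of 1.11. Small changes that did not pass are still not shown to be absent.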

Other observations

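The grouping of genes by the start of their symbols, the neighbour tests, the tests on shared sequence and protein starts, and the thinned and offset fits were all chosen after the data were seen. Among 172 families of genes whose symbols start alike the camera test called 17, and 0 with an estimated correlation. All 11 tested UTP genes, whose products process the small ribosomal subunit, fell, with a median log2 fold change of -0.28 (camera with Benjamini-Hochberg adjustment, adjusted p = 3.74e-06, but adjusted p = 0.671 with an estimated correlation). Of 33 POLR genes, subunits of RNA polymerases, 21 fell and 2 rose (camera, adjusted p = 3.96e-05, but adjusted p = 0.671 with an estimated correlation). Mitochondrial ribosomal protein genes fell in 29 of 49 cases for MRPL and 20 of 29 for MRPS, and none rose, while 11 of 15 TIMM genes, which import proteins into mitochondria, fell. Of 21 PDE genes, most of them cyclic nucleotide phosphodiesterases, 9 rose and 4 fell, and of 34 KIF genes, which encode kinesin motors, 15 rose and 4 fell.

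Genes that rose at least 2-fold, and those that fell at least 2-fold, lay side by side more often than in permutations. Around PDCD1 on chromosome 2, GAL3ST2, a sulfotransferase gene, and NEU4, a sialidase gene, rose by 1.18 ± 0.15 and 2.96 ± 0.13, and RTP5, a receptor transporter gene, by 3.01 ± 0.10, next to the rise of 1.17 ± 0.05 of PDCD1. ECEL1 and PRSS56 adjoin on the same chromosome, and LGALS12 adjoins PLAAT5, a phospholipase and acyltransferase gene that rose by 2.65 ± 0.08. TGFBR3, a TGF-beta coreceptor gene, and BRDT, a bromodomain gene of the testis, rose by 2.32 ± 0.08 and 2.08 ± 0.15. Pairs were adjacent among tested genes only, so untested genes may lie between them. Of 15233 such pairs within 50000 bp, 42 had both genes risen at least 2-fold. The median was 4 when the calls of such a rise were permuted within 20 expression bins (permutation p = 1e-04, the smallest possible with 10000 permutations). In 7 pairs, 4 of them not overlapping, both genes fell at least 2-fold, against a median of 0 (permutation p = 1e-04). These genes were named after their values were seen.

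Reads shared by overlapping gene models could raise neighbours together, but 23 of the 10458 pairs that do not overlap had both genes risen, where the central 95% of permutations reached 6. Transcription running past the end of an upstream gene could do so on 1 strand, yet 9 pairs on opposite strands did and the central 95% of permutations reached 4. In pairs whose starts face each other, transcription running past the end of either partner leads away from the other. Of 2417 such pairs, 6 had both genes risen where the central 95% of permutations reached 2. Another gene upstream on the same strand, tested or not, could still run into a partner, as NEU4 could into RTP5 beyond PDCD1. Transcription from outside a pair is therefore not excluded, for these pairs or for those on opposite strands. A shared regulatory element or chromatin domain is a hypothesis that these counts cannot test.

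Reads shared between tubulin paralogs and pseudogenes could spread the fall of an abundant member to others. However, TUBB, TUBA1B and TUBB4B fell by more CPM than all genes sharing an identical 75-base word with them held together in vehicle. These were 3 of the 11 genes, and for the other 6 that fell this explanation stays open. The comparison used exact matches and deposited counts, in which shared reads may already be moved or missing. Read sharing is therefore not excluded for these 3 genes either. Free tubulin is known to trigger decay of messenger RNAs whose protein starts with MREC or MREI, which all 11 genes can encode and the gamma-, delta- and epsilon-tubulins do not. The median log2 fold change of those 4 genes was 0.0275, but TUBG1 fell among them and TUBA8 and TUBB3 did not fall. The decay explanation may therefore hold only in part. TUBA8 and TUBB3 weigh little here, with means over both groups of only 1.43 and 0.679 CPM. Both also have annotated proteins with other starts, as do TUBB and TUBA1B, which fell. Counts over exons cannot separate decay from lower transcription. Outside the tubulins the only tested gene with such a start was MBTPS1, a protease gene that activates sterol-sensing factors, and it rose by 0.43, within the -0.339 to 0.512 of 95% of sets of similar abundance, while the tubulin-like TUBAL3 had -0.48 ± 0.07. That meets the bound set in advance against the start alone being enough, but the bound was wrong for 1 gene that also has annotated proteins starting with MKLV, since counts per gene cannot show which messenger RNA was measured.

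The depth difference between the groups could add small differences, but with every library thinned to 1 total 8429 genes passed, 8220 of them among the 8515. A trend with gene length or GC content could do the same, and with each library's trend removed 9082 genes passed, of which 7994 were shared. Of the 8515 genes 41 changed sign, whether or not they passed there, and the balance moved to 3885 higher and 5197 lower. Across genes the log2 fold change had correlations of 0.0581 with log2 exon length and -0.0108 with GC content. The grouping itself could be weighed only by 10 splits of the libraries into 3 and 3, too few for a share under 0.05. The real split gave 8515 genes and the highest other 1. Every other split mixes treated and vehicle libraries in both of its groups, so the treatment difference itself widens the spread and lowers the count. That contrast was therefore largely fixed in advance, and no conclusion is drawn from it.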
